A study of Mus musculus with 3 samples.

How the data were processed

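Gene expression was measured in long-term haematopoietic stem cells (LT-HSCs), the rare bone marrow cells that renew the blood over the long term. The cells came from female C57Bl/6 mice that were left non-irradiated or had received total body irradiation (TBI) of 8 Gy, either at CDR or as FLASH. FLASH is delivery of a dose at an ultra-high dose rate. CDR was read as conventional dose rate from general use, since the labels do not spell it out. Per the labels' protocols, 10000 LT-HSCs were isolated from marrow 15 days after TBI, and total RNA was labelled with biotin by the Affymetrix whole transcript sense target assay for hybridisation. The gate used to sort the cells and the number of mice behind each sample are not given in the sources used here. Each of the 3 groups had 1 array.

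The deposited table holds the authors' processed level of each probe set on a log scale, taken here as log2 from its range of values. Partek is named in the submitters' processing notes, with no version. The background correction, summarisation and normalisation are not given in the sources used here. The table has 25206 probe sets, of which 23185 carried 1 gene symbol in the platform's probe table, 0 carried several and 2021 were not listed there and stayed unnamed. Each named probe set belonged to a different gene, and its identifier was the Entrez gene identifier. All 23185 symbols equalled those of the RefSeq gene table. Over all 25206 probe sets, array medians were 4.66 for non-irradiated, 4.62 for CDR and 4.62 for FLASH.

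An exact tie between arrays was common in the deposited values. All 3 arrays held the same value for 39.8% of probe sets, and the FLASH and CDR arrays did for 54.05%. Such ties bear on every median: the median of a random gene list is mostly at or near 0, and a very small list median can then stand apart. Where a list stood apart by its median and not its mean, or the reverse, the text therefore says so.

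Values were used as deposited, and a difference between arrays is the difference of log2 values. A gene was called detected in a comparison when the array with the higher value read above the 95th percentile, on that array, of 1364 olfactory, vomeronasal and trace amine receptor genes taken as unexpressed. This detection level was 4.15 on the non-irradiated array, 4.16 on the CDR array and 4.22 on the FLASH array. Where the dimmer array lay under its level, the fold is given as a lower bound against that level ("at least N-fold"). Detected genes at least 2-fold higher or lower were counted on deposited values, also where the dimmer array lay under its level. Such a count can hold genes whose lower bound is under 2-fold, and counts with those dim values raised to the level were added after seeing the data. No test was possible with 1 array per group, and the number of arrays limits the precision of every value.

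Before the data were examined, 36 gene lists were fixed for blood lineages, stem cell programmes, DNA repair, stress and metabolism, and 35 of them had at least 4 measured members. For each list the median difference was placed among 10000 random lists of the same size, matched on mean level in 20 bins. A list is said to stand apart when it lay in the outer 2.5% on either side. This percentile describes these arrays and does not test the conditions. If all list members varied independently, about 1.75 of the 35 lists would stand apart in a comparison. Members of a list can move together and some genes stand in several lists. That number is therefore not the count to be met by chance on these arrays. Genes named in the text follow a rule fixed at the same time: the 10 largest differences in each direction per comparison among detected genes, without gene models, predicted or pseudogenes by symbol, microRNA, small nucleolar RNA, histone, olfactory or vomeronasal receptor, T cell receptor or antibody segment genes, up to 2 members per direction of each list described, and Cdkn1a, Mdm2, Ccng1, Kit, Procr, Slamf1, Cd48, Cd34, Flt3 and Mki67. Other genes are named as chosen after their values were seen.

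The alternatives were median centring, quantile normalisation and cyclic loess with limma 3.58.1 in R 4.3.3, an offset of 32 added before the log, no filter, a stricter filter (mean level above the 99th percentile of the unexpressed genes), fold thresholds of 1.5 and 3, list means, and detected members only. Median centring used each array's median over the 23185 named genes, not its median over all probe sets. Counts without antibody and T cell receptor segments, and with protein-coding genes only, were added after seeing the data. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

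The steps were tested on simulated data for the FLASH and CDR arrays, with 23185 genes and a noise SD of 0.223 per array, taken from all differences with segments included. The genes given a change were drawn from those with a mean level well above the detection level, so that dim genes are not covered. Of 50 genes simulated at each size, 25 were counted at a true fold of 2, 49 at 3, 50 at 4 and 50 at 8. Of 22985 unchanged genes 36 were counted. A second simulation, added after the results were seen, took its noise SD of 0.124 from genes outside segments and counted 0 of 22833. Both used normal noise without replicates to set its size or shape, so that neither gives a false count for the real arrays. Of 33 unshifted lists 0 stood apart, and both shifted lists did. The shift was larger than many of the list medians given here, and list members had independent noise. Calls on small medians, or on members that move together, are therefore not covered. The simulated values had no exact ties, so that this step does not cover the effect of ties on medians.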

Results

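Expression profiles of LT-HSCs were compared between non-irradiated mice, mice given 8 Gy TBI at CDR and mice given 8 Gy TBI as FLASH. The irradiated mice were studied 15 days after irradiation. Each group had 1 array. No difference reported here therefore has a replicate check, and "higher" and "lower" describe these arrays. The number of genes above the detection level was 13316 on the non-irradiated array, 13200 on the CDR array and 13054 on the FLASH array. Y-linked genes, which these female mice lack, read at most 3.18, 2.98 and 3.01 on the respective arrays, under the detection level of each. The 14 measured housekeeping genes had a median log2 difference of 0.06 on both irradiated arrays against the non-irradiated one, ranging on the CDR array from -0.22 (Srp14) to 0.44 (Gusb).

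The comparison of the CDR and non-irradiated arrays asked how LT-HSC expression stood 15 days after irradiation at CDR. Genes of stem cell identity and of the immediate early response were lower on the CDR array, while genes of the red cell lineage, mitosis and ribosome assembly were higher. Of 13448 detected genes, 103 were at least 2-fold higher and 317 at least 2-fold lower by their deposited values, and 91 and 288 when dim values were raised to the detection level. Among the lower genes 199 were protein coding and 96 were antibody or T cell receptor segments. Of the 1364 genes taken as unexpressed, 1 was at least 2-fold higher and 3 were at least 2-fold lower.

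Stem cell identity genes were at least 2-fold lower on the CDR array for 12 of 36 detected members and within 2-fold for 24, with 0 at least 2-fold higher. Their median difference was -0.65 (1.56-fold), lower than in any of the 10000 matched random lists. The cation channel gene Trpc6 was lower by a log2 difference of -2.27 and Pdzk1ip1 by -2.21. Hlf, a transcription factor of stem cell maintenance, stood at -2.0 and Procr, the stem cell surface marker EPCR, at -1.73. Slamf1, the marker CD150, read -0.02 and Kit, the stem cell factor receptor, -0.47. Clca3a1 was the exception among these, at 0.70. Of 23 immediate early genes, rapid-response factors that are also induced by tissue handling, 8 were at least 2-fold lower and 15 within 2-fold, with Nr4a1 at -1.97 and Egr1 at -1.70. The quiescence list also holds cyclin D and cyclin-dependent kinase genes that drive the cell cycle. Its median was -0.13, with 2 of 21 members at least 2-fold lower. Those were Nr4a1 and Egr1, which stand in both lists. Its member Ccnd1, cyclin D1, was at 0.71.

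Megakaryocyte genes had a median of -0.25 on the CDR array, with 3 of 19 detected members at least 2-fold lower, among them Mmrn1 at -1.95 and Thbs1, which read under the detection level on CDR, at least 2.44-fold lower. Multipotent progenitor genes had a median of -0.15 and 4 of 18 at least 2-fold lower, including Dntt, the DNA polymerase of lymphoid receptor rearrangement, at -2.68, Ly6d at -1.91 and the cytokine receptor Flt3 at -1.05. Cd48 was at 0.47 and Cd34 at -0.34. B cell genes had a median of -0.10 with 4 of 13 at least 2-fold lower, led by Dntt and by Ighm at -1.34. MHC class I genes had a median of -0.13, with 11 of 13 members within 2-fold. The 2 at least 2-fold lower were H2-T23 at -1.43 and H2-Q7 at -1.37, while B2m read -0.07.

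Erythroid genes were higher, with a median of 0.56 (1.47-fold), 7 of 24 detected members at least 2-fold higher, 17 within 2-fold and 0 at least 2-fold lower. Rhag was at 1.62 and the beta globin gene Hbb-bs at 1.51, while Car2 was at -0.28. Mitotic genes differed little one by one and in the same direction, with 38 of 39 higher, 0 lower and a median of 0.40. The mitotic kinase genes Plk1 and Bub1 were at 0.91 and 0.82, and Mki67 was at 0.36. DNA replication genes were higher for 37 of 40 members, led by Rrm2, a ribonucleotide reductase subunit, at 1.12 and Ccne1, cyclin E1, at 1.1. Ribosome biogenesis genes were higher for 30 of 31 members, with a median of 0.34 and Nolc1 at 0.75. The unfolded protein response list had a median of 0.24 with Asns at 1.21 and Ero1a at 1.1. Homologous recombination and Fanconi genes had a median of 0.11, nuclear oxidative phosphorylation genes 0.12, cytosolic ribosomal protein genes, whose many pseudogenes make single values uncertain, 0.07, and heat shock genes 0.15.

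The p53 target list had a median of 0.00, with 23 of 26 detected members within 2-fold. Cdkn1a, the p21 cell cycle inhibitor, was at 0.05, Mdm2 at -0.06 and Ccng1 at 0.00, while Ddit4 and Plk2 were lower at -1.11 and -1.09. In all, 19 of 35 lists stood apart by their medians, 9 above and 10 below their random lists, and 17 did by their means. Heat shock, aged stem cell, mast cell and interferon-stimulated genes stood apart by the median and not by the mean. The medians of the last 3 of these were -0.023, -0.036 and -0.049. Each sign turned when the arrays were centred on the medians of named genes, a constant shift that leaves the percentiles as they were. Monocyte and dendritic cell genes and BCL2 family genes stood apart above by the mean alone.

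The 10 largest positive differences belonged to Asb17os (2.23), Lcn2 (2.17), Tfb2m (2.16), Tpsb2 (2.0), Clec5a (1.99), Nxpe2 (1.98), Rbm3 (1.97), Ccnyl1 (1.86), Pnp2 (1.85) and Cldn13 (1.68). Lcn2 encodes the neutrophil granule protein lipocalin 2 and Tpsb2 a mast cell tryptase. Tfb2m, Tpsb2 and Rbm3 were under the detection level on the non-irradiated array, so that their folds were at least 2.66, 3.34 and 2.72. The 10 largest negative differences belonged to Myl10 (-2.86), Bex1 (-2.78), Prss34 (-2.71), Ltb (-2.69), Dntt (-2.68), Apol7e (-2.68), Rab6b (-2.42), Trpc6 (-2.27), S100a9 (-2.25) and Clic5 (-2.22). Apol7e and Rab6b were at least 2.5-fold and 3.09-fold lower. The granulocyte list pointed both ways, with Lcn2 and Cebpe (0.88) higher, S100a9 lower, and Camp at least 3.35-fold lower.

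**Figure D1:**
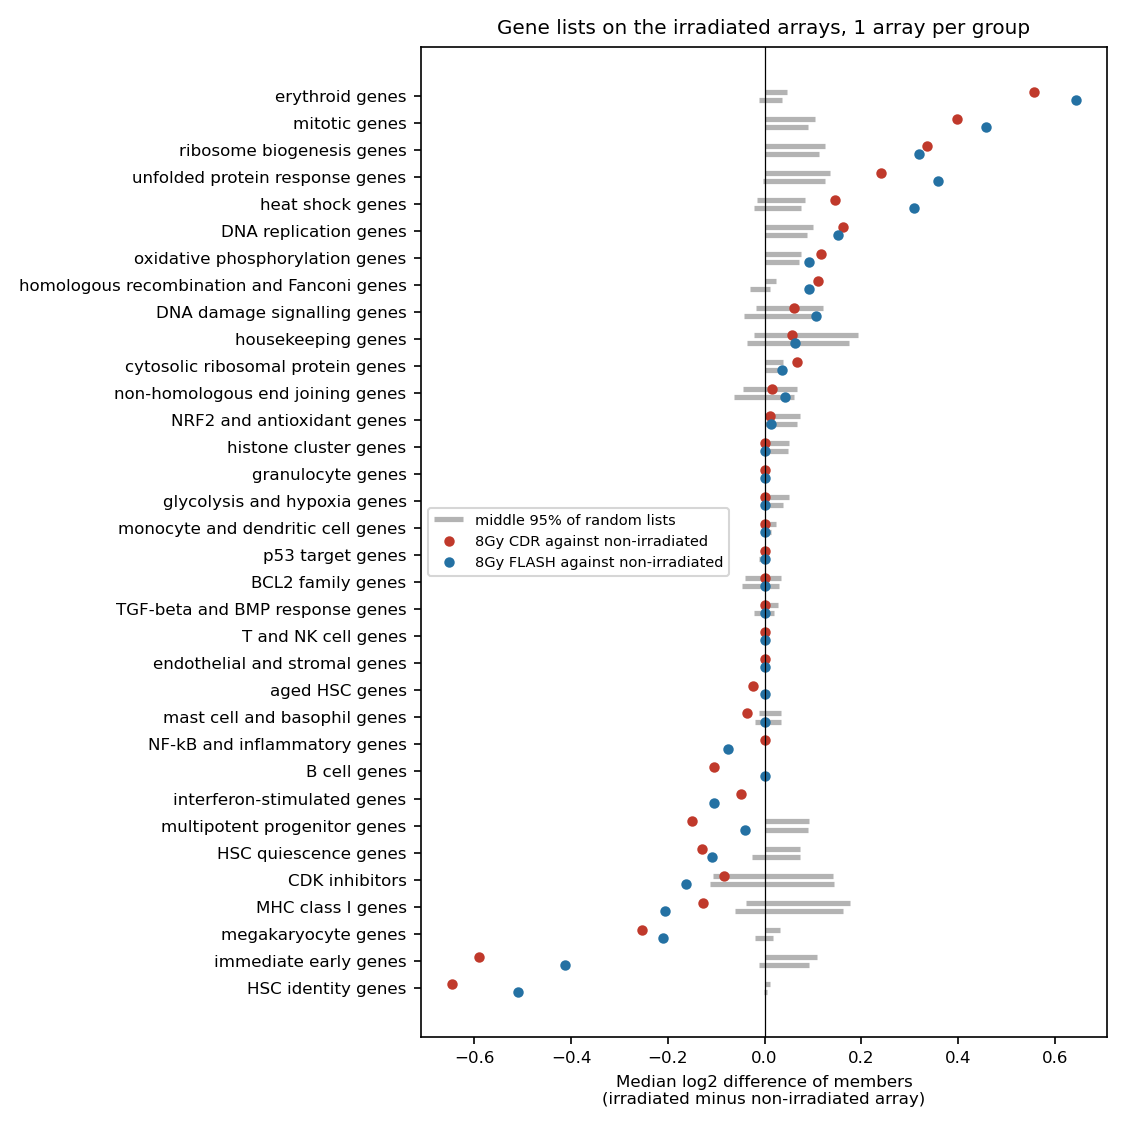
Median log2 difference of each gene list (horizontal axis) on the CDR array (red) and the FLASH array (blue) against the non-irradiated array, with 1 array per group; grey bars span the middle 95% of 10000 matched random lists and vanish where that range has no width. Erythroid genes lie at 0.56 and 0.64 and stem cell identity genes at -0.65 and -0.51; the small medians of aged stem cell, mast cell and interferon-stimulated genes on the CDR array change sign under median centring.

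The comparison of the FLASH and non-irradiated arrays asked the same of irradiation at an ultra-high dose rate. The FLASH array was also lower in stem cell identity and immediate early genes and higher in erythroid, mitotic and ribosome biogenesis genes. Heat shock genes were higher as well, and single dendritic cell markers such as Clec9a (2.15) were among the largest positive differences. Of 13288 detected genes, 155 were at least 2-fold higher and 233 at least 2-fold lower by their deposited values, and 138 and 210 with dim values raised to the detection level. Antibody and T cell receptor segments made up 40 of the higher and 44 of the lower genes, and protein-coding genes 101 and 162. Of the 1364 unexpressed genes, 1 was at least 2-fold higher and 3 were at least 2-fold lower.

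Of 36 stem cell identity genes, 7 were at least 2-fold lower on the FLASH array, 28 were within 2-fold and 1, Clca3a1 at 1.40, was at least 2-fold higher. The median was -0.51 (1.42-fold). Hlf was at -1.90, Mmrn1 at -1.89, Procr at -0.82, Kit at -0.87 and Slamf1 at 0.11. Immediate early genes had a median of -0.41 with 5 of 23 at least 2-fold lower, among them Nr4a1 at -2.30 and Egr1 at -1.52, while Atf3 was at 0.59. The mixed quiescence list had a median of -0.11, megakaryocyte genes -0.21 and multipotent progenitor genes -0.041. Dntt was at -2.09, Flt3 at -1.47, Cd34 at -0.44 and Cd48 at 0.34. Interferon-stimulated genes had a median of -0.10, with 25 of 38 detected members lower and 2 higher, and Rsad2, the antiviral protein viperin, at least 2.91-fold lower. MHC class I genes had a median of -0.21, with 11 of 13 members within 2-fold and H2-T23 at -1.69.

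Erythroid genes had a median of 0.64 (1.56-fold), with 8 of 24 detected members at least 2-fold higher and 0 at least 2-fold lower. Ermap was at 1.73 and Hbb-bs at 1.68. Mitotic genes had a median of 0.46, with 38 of 39 members higher, 0 lower and Plk1 at 1.09. Mki67 was at 0.36. DNA replication genes had a median of 0.15, with Ccne1 at 1.29 and Rrm2 at 1.21. Ribosome biogenesis genes had a median of 0.32, and the unfolded protein response list 0.36 with Asns at 1.1. Heat shock genes had a median of 0.31, with the inducible chaperone genes Hspa1b at least 1.80-fold higher and Hsph1 at 1.17. Homologous recombination and Fanconi genes had a median of 0.092, oxidative phosphorylation genes 0.092 and ribosomal protein genes 0.036.

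Among 25 detected monocyte and dendritic cell genes, 5 were at least 2-fold higher on the FLASH array and 0 at least 2-fold lower. The MHC class II gene H2-Eb1 was at 2.36 and Clec9a, a receptor of type 1 dendritic cells, at 2.15, while Csf1r, the macrophage colony-stimulating factor receptor, was at -0.78 and Hmox1 at -0.70. The list's median was 0.00, with 11 members higher and 10 lower, but its mean of 0.28 stood apart, as its mean of 0.15 did on the CDR array. Endothelial and stromal genes also stood apart by the mean alone, with Plvap at 1.12, Sparc at 1.07 and Emcn at -0.99. Of its 13 detected members, 2 were at least 2-fold higher with dim values raised to the detection level. BCL2 family genes did so through Bcl2a1b at 2.84 and Bcl2a1a at 1.59, near-identical copies whose signals cannot be separated with confidence. Granulocyte and B cell genes stood apart below by the mean alone. CDK inhibitor, DNA damage signalling and inflammatory genes stood apart by the median alone, at -0.16, 0.11 and -0.075. In all, 19 of 35 lists stood apart by medians, 10 above and 9 below, and 21 by means. The p53 target list had a median of 0.00, with Cdkn1a at -0.18, Mdm2 at -0.06, Ccng1 at 0.00 and Ddit4 at -1.61.

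The 10 largest positive differences belonged to Tpsb2 (2.92), Bcl2a1b (2.84), Ifi205 (2.59), Plbd1 (2.58), Naaa (2.39), H2-Eb1 (2.36), Clec9a (2.15), Gpr141b (2.12), Nxpe2 (2.09) and Tcp10c (2.09). Tpsb2, Ifi205, Gpr141b and Tcp10c were under the detection level on the non-irradiated array and at least 6.31-fold, 4.99-fold, 3.69-fold and 1.38-fold higher. The 10 largest negative differences belonged to Myl10 (-2.86), Rnu7 (-2.76), Apol7e (-2.73), Wfdc17 (-2.69), Rab6b (-2.33), Nr4a1 (-2.30), Pcdhgb5 (-2.23), Dntt (-2.09), Clic5 (-2.06) and Gprc5b (-2.01). Rnu7, Apol7e, Rab6b and Pcdhgb5 were at least 4.21-fold, 2.41-fold, 2.98-fold and 1.38-fold lower.

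**Figure D2:**
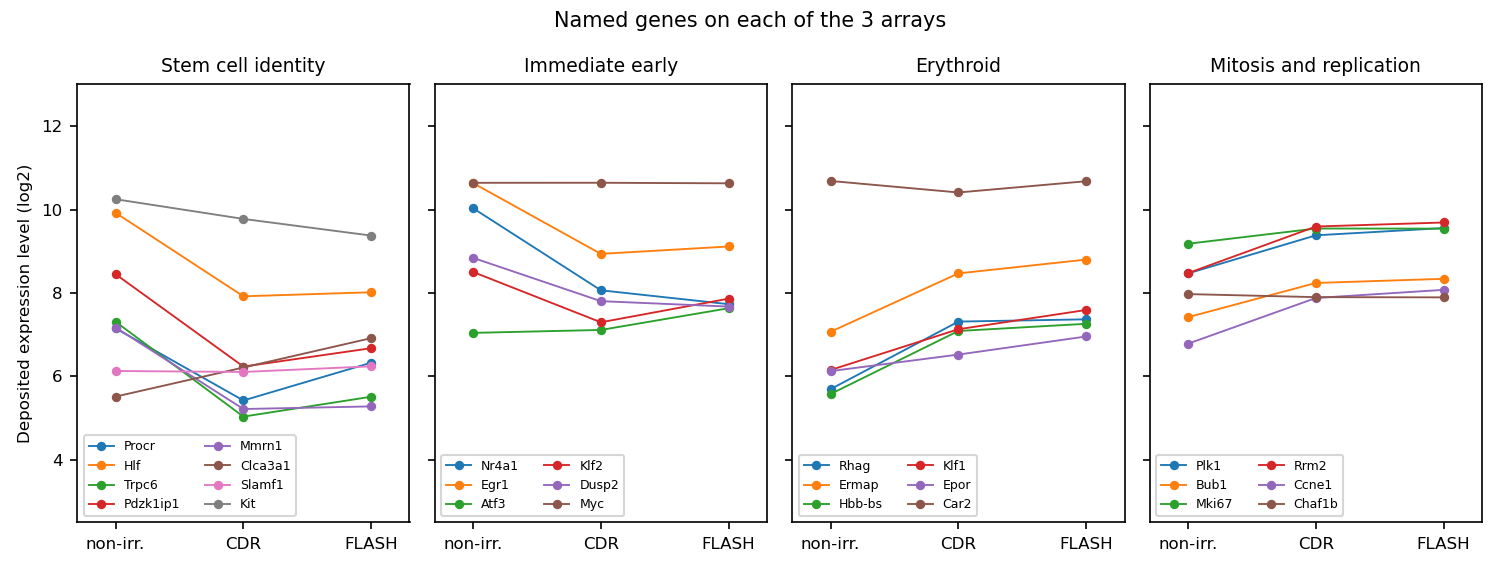
Deposited level (log2) of named genes on the non-irradiated, CDR and FLASH arrays, 1 point per array; lines join the 3 values of a gene and do not stand for a series. Hlf read -2.0 and -1.90 and Rhag 1.62 and 1.67 against the non-irradiated array on the CDR and FLASH arrays, while Slamf1 read -0.02 and 0.11.

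The irradiated arrays were set against each other as departures from the same non-irradiated array. Across 13514 genes detected in either comparison, the differences correlated with Pearson's r of 0.717, and with 0.868 without antibody and T cell receptor segments. Genes are not independent replicates, and the shared non-irradiated array alone gave a mean r of 0.499 in 100 simulations with no effect. The covariance was 0.123, against 0.0489 simulated. Of these genes, 70 were at least 2-fold higher on both irradiated arrays, out of 104 on the CDR and 157 on the FLASH array. Independent lists of those sizes would share 1.21 genes and the simulations without effect shared 0.39. In the other direction 186 were at least 2-fold lower on both, out of 319 and 233, against 5.5 for independent lists and 0.46 simulated. Part or all of the excess may come from the shared array, which could not be split. The simulations used normal noise of equal size on each array and had no ties. At least 2-fold differences in opposite directions were found for 16 genes, all of them antibody or T cell receptor segments. With dim values raised to the detection level, 64 genes were higher on both, 170 lower on both and 12 in opposite directions, each at least 2-fold.

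The comparison of the FLASH and CDR arrays asked whether the dose rate went with a difference at the same dose. The FLASH array was higher in many antibody gene segments, and stem cell identity genes were slightly higher on it. Outside the segments, Jchain, H2-Eb1, Cd74 and Bcl2a1b were among the largest positive differences. Of 13184 detected genes, 112 were at least 2-fold higher and 19 at least 2-fold lower by their deposited values, and 100 and 17 with dim values raised to the detection level. Segments of antibody and T cell receptor genes made up 84 of the higher and 7 of the lower genes. Without these segments 28 genes were at least 2-fold higher and 12 at least 2-fold lower, and 23 and 11 with dim values raised. In simulations, 36 of 22985 unchanged genes passed 2-fold when the noise was as wide as all differences, segments included. In a simulation added after the results were seen, with that width taken outside segments, 0 of 22833 did. Neither is a measured noise level, and single genes outside the segments are therefore uncertain. Of the 1364 unexpressed genes, 0 were at least 2-fold higher and 1 was at least 2-fold lower.

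Antibody V segments, the gene parts that encode variable regions, differed widely between the arrays. Of 119 detected segments, 76 were at least 2-fold higher on the FLASH array and 6 at least 2-fold lower, or 70 and 5 with dim values raised to the detection level. Their log2 differences ran from -4.24 to 6.32 in deposited values. Against the non-irradiated array, 81 of 121 were at least 2-fold lower on the CDR array and 6 at least 2-fold higher, while the FLASH array had 39 in each direction of 133. Of T cell receptor V and J segments, 2 of 32 were at least 2-fold higher on FLASH than on CDR, or 1 with dim values raised, and 0 at least 2-fold lower. T cell receptor constant regions were at least 2-fold lower on the CDR array for 4 of 5 detected and on the FLASH array for 2 of 6, against non-irradiated in deposited values, with a median of 0.49 between FLASH and CDR. Of 6 detected antibody constant regions, 2 were at least 2-fold higher on FLASH than on CDR and 1, Ighg2b, at least 4.70-fold lower, with a median of 0.28 in deposited values. Jchain, the joining chain of secreted antibodies, was 1.72 higher on the FLASH array, Ighm, the IgM constant region, 1.15 higher, and Pou2af1, a B cell coactivator, 1.46 higher. Jchain was at -2.14 on CDR and -0.41 on FLASH against the non-irradiated array, Pou2af1 at -1.03 and 0.43, and Ighm at -1.34 on CDR. The B cell list, which holds Ighm and Pou2af1, had a median of 0.076 and 2 of 13 members at least 2-fold higher, while Cd79b of the B cell receptor was at -0.52.

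**Figure D3:**
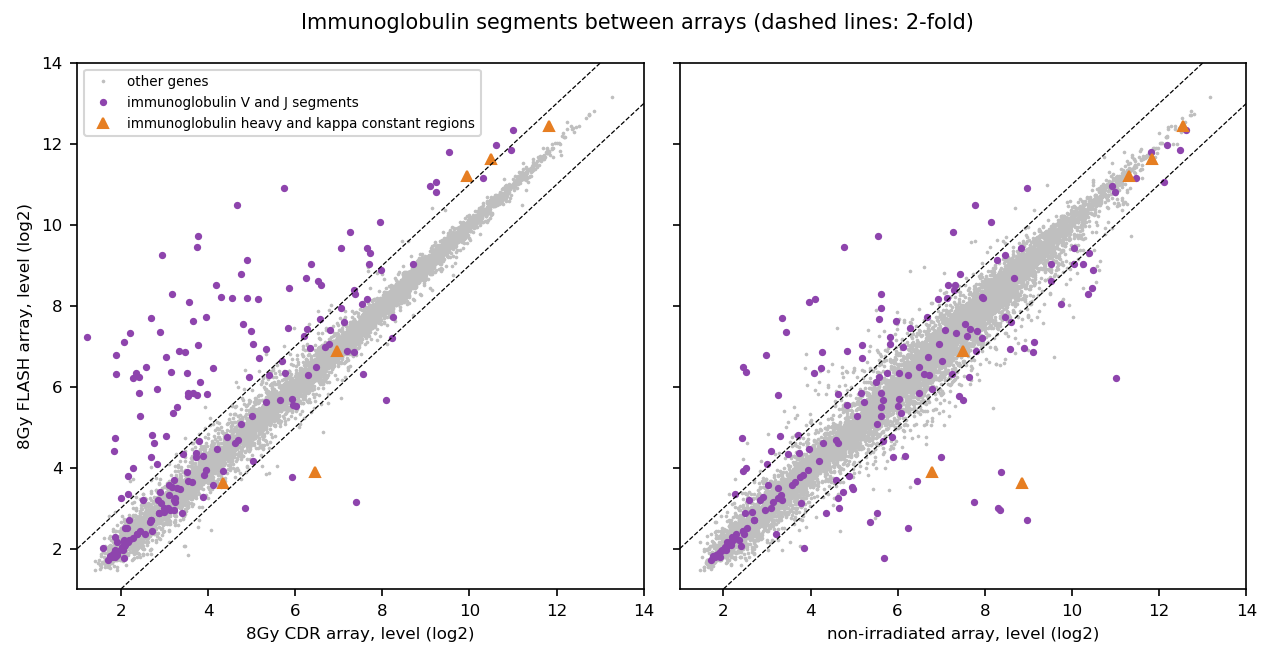
Level (log2) of each gene on the FLASH array (vertical axis) against the CDR array (left) and the non-irradiated array (right); purple points are antibody V and J segments, triangles heavy and kappa constant regions, grey points other genes, and dashed lines mark 2-fold. Against CDR, 76 of 119 detected V segments lie at least 2-fold above and 6 at least 2-fold under the diagonal.

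Stem cell identity genes were higher on the FLASH than on the CDR array for 26 of 36 members and lower for 3, with a median of 0.10 (1.07-fold) that stood apart by median and mean. All 36 were within 2-fold, and 3 were at least 1.5-fold higher, led by Procr at 0.91 and Clca3a1 at 0.70. Kit was at -0.40. Interferon-stimulated genes had a median of 0.00 and a mean of -0.085, which stood apart below, with Oas1a at -0.61. By medians 11 of 35 lists stood apart, 9 above and 2 below, but by means only the stem cell identity, B cell and interferon-stimulated lists did, 3 in all. Immediate early genes (median 0.17), erythroid genes (0.16), heat shock genes (0.12) and mast cell genes (0.036) stood apart by the median alone, as did granulocyte genes (-0.072) and inflammatory genes (-0.027). So did the medians of mitotic genes (0.031), monocyte and dendritic cell genes (0.0084) and unfolded protein response genes (0.0061). Each was smaller than the constant by which centring on the medians of named genes moves all genes. Over all probe sets the FLASH and CDR medians were both 4.62. The sign of each list median therefore depends on the choice of centring, and its percentile does not. The CDK inhibitor list did not stand apart, with a median of 0.0077, which was -0.025 after centring, and a mean of -0.0074.

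Of 25 detected monocyte and dendritic cell genes, 4 were at least 2-fold higher on the FLASH array and 1, Csf1r at -1.01, was at least 2-fold lower. H2-Eb1 was at 1.31 and Cd74, the MHC class II invariant chain, at 1.28, while Ccr2, a monocyte chemokine receptor, was at -0.87. The other genes fixed in advance differed little: Cdkn1a was at -0.23, Flt3 at -0.42, Slamf1 at 0.13, Cd48 at -0.13, Cd34 at -0.10, Mdm2 at 0.00 and Mki67 at 0.00. The 10 largest positive differences belonged to Jchain (1.72), Tnfsf13 (1.57), Slamf7 (1.55), Rhoc (1.47), Bcl2a1b (1.46), Pou2af1 (1.46), Prss34 (1.33), H2-Eb1 (1.31), Bcl2a1a (1.31) and Cd74 (1.28). The 10 largest negative differences belonged to Smim40 (-1.53), Sarnp (-1.32), Defa40 (-1.21), Ly6a2 (-1.05), Vaultrc5 (-1.05), Csf1r (-1.01), Vamp1 (-0.98), Wfdc17 (-0.96), Mrgpra2a (-0.94) and Rpl5 (-0.89). Rpl5 belongs to a family rich in pseudogenes and is uncertain, and Tnfsf13 was at least 2.54-fold higher on FLASH because the CDR array read it under the detection level. Smim40 and Defa40 read under it on the FLASH array and were at least 2.27-fold and 2.04-fold lower.

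Lists of non-homologous end joining, NRF2 and antioxidant, glycolysis and hypoxia, histone cluster, TGF-beta and BMP, and T and NK cell genes did not stand apart in any of the 3 comparisons, by medians or by means. Polq, the end-joining polymerase, was at 0.41 on both irradiated arrays, Gsr at 0.87 on CDR and 0.49 on FLASH, and Id1 at 1.13 on both. Of mitochondrially encoded genes 0 were measured.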

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

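The tests of antibody-secreting cells, of diluted stem cells, of the single non-irradiated array and of monocytes were chosen after the result was seen, as was the mean beside the median for dendritic cell markers.

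Genes whose differences from the non-irradiated array had opposite signs on the irradiated arrays stood out among those named, and the difference was not tested. In FLASH minus CDR values, Tnfsf13 was at 1.57, Slamf7 at 1.55, Rhoc at 1.47, Pou2af1 at 1.46 and Mrc1 at 0.89, each lower on CDR and higher on FLASH than on the non-irradiated array. Smim40 at -1.53, Sarnp at -1.32, Ly6a2 at -1.05, Csf1r at -1.01 and Vamp1 at -0.98 went the other way. Tnfsf13 on CDR and Smim40 on FLASH read under the detection level, so that their folds were at least 2.54 and 2.27. Probe sets without a gene name, which no comparison used, also differed: 13 of 1123 detected were at least 2-fold higher and 24 lower on the CDR array, and 13 of 1105 higher and 23 lower on the FLASH array. Named detected genes had similar shares, 0.77% higher and 2.36% lower on CDR and 1.17% and 1.75% on FLASH. The unnamed probe sets therefore did not stand out.

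Antibody segments differed between the FLASH and CDR arrays far more than other genes. Noise of short segments on the array was argued against by T cell receptor segments, whose SD was only 0.165 times that of antibody segments. Of 146 T cell receptor V and J segments 32 were detected, and the antibody and receptor segments were not matched on level. Noise that depends on level is therefore not covered. Signal shared across whole families of V segments, grouped by symbol, was argued against by an SD within families of 0.974 times that of all segments. No probe sequences were at hand, so that signal shared by single near-identical segments of a family is not covered. RNA of antibody-secreting cells in the sorted samples may be the source: 4 of 4 abundant products (Igkc, Ighm, Igha and Jchain, all detected on each array, Ighm also in the B cell list) were at least 1.5-fold higher on FLASH, with Igkc at 12.46 against 11.82 and Igha at 11.21 against 9.95. The 4 products had a median of -1.35 on CDR and -0.15 on FLASH against the non-irradiated array. All 4 were at least 1.5-fold lower on CDR and 0 were on FLASH, so that CDR departed more from it. The test of these 4 products came after Jchain and Ighm had been seen to be higher. Ighg2b went the other way at least 4.70-fold, which a larger share of like cells does not account for. A wider list of antibody-secreting cell genes stood apart above by its median (0.12) and by its mean (percentile 99.67), with 4 of 14 detected members at least 1.5-fold higher. The 6 pan-B cell genes had a median of 0.00, but only 3 of them were detected. A gate against lineage markers would remove most such cells, the gate is not given in the sources used here, and whether dose rate or the draw of a few clones set the difference stays open with 1 array per group.

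Stem cell identity genes were lower on both irradiated arrays. Even replacement of stem cells by all other marrow cell types was taken to raise every lineage list median. Instead 5 of 12 lay in the lowest 2.5% of random lists (7 of 12 by means), while erythroid genes were higher at 0.56 and 0.64. The low medians were those of megakaryocyte and multipotent progenitor genes on both irradiated arrays and of B cell genes on CDR. Only genes shared with the stem cell list were left out, so that other genes which stem cells also express could fall with them. The test therefore cannot decide on such replacement. A larger share of erythroid or cycling progenitors, and lower expression within stem cells, were not tested and stay open. A peculiarity of the single non-irradiated array cannot be told apart from an effect of irradiation, since both differences rest on that 1 array.

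A set of 10 type 1 dendritic cell and MHC class II genes, picked from the ranking for being high, had a median of 2.03 on FLASH and 0.996 on CDR against non-irradiated, while the fixed monocyte and dendritic cell list had 0.00 on both and 0.0084 between FLASH and CDR. A larger share of monocytes and macrophages on FLASH than on CDR was argued against by monocyte genes, whose detected members had a median of -0.51 at percentile 0.0 of random lists, and of -0.34 at percentile 0.01 without Csf1r and Ccr2, which had been seen to be lower. On CDR against non-irradiated the monocyte list lay above at percentile 98.46, but without these 2 genes its median was 0.00, so that such a share stays open there. Type 1 dendritic cells or their precursors may contribute: 16 further markers not looked at before had a median of 0.037 at percentile 99.82, which met the bound set in advance. That bound is passed by very small medians where most differences are tied at 0, the mean lay at percentile 96.17, and only 3 of 14 detected markers were at least 1.5-fold higher, so that this explanation stays open.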

How the results depend on the processing

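Counts restricted to protein-coding genes, without antibody and T cell receptor segments, or with the detection level as a floor were chosen after seeing the data. No paired analysis was possible because each group had 1 array. The mean of a gene's probe sets and the probe set with the smallest difference were not run, since each gene had 1 probe set. Counts are given in the order CDR against non-irradiated, FLASH against non-irradiated and FLASH against CDR, higher then lower. With an offset of 32, which shrinks dim genes by construction, they were 45 and 152, 78 and 101, and 73 and 5. A fold threshold of 1.5 gave 430 and 724, 477 and 704, and 244 and 103, and a threshold of 3 gave 20 and 127, 59 and 74, and 68 and 6. The stricter filter, which tests fewer genes, moved FLASH against CDR to 68 and 10. Protein-coding genes alone gave 199 lower for CDR, 101 higher for FLASH against non-irradiated, and 27 and 8 for FLASH against CDR. Without segments FLASH against CDR gave 28 and 12, and the correlation of the irradiated arrays' differences was 0.868, against 0.739 with the stricter filter. Other normalisations, no filter and the floor kept every count over all genes within 1.5 times.

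List means in place of medians left 3 lists apart between FLASH and CDR. Centring the arrays on the medians of named genes shifted differences by at most 0.0574. This shift of all genes alike turned the sign of 6 small medians of lists that stood apart and left the percentiles as they were. For CDR against non-irradiated these were aged stem cell (0.034), mast cell (0.021) and interferon-stimulated genes (0.0088). For FLASH against CDR they were mitotic (-0.0021), monocyte and dendritic cell (-0.024) and unfolded protein response genes (-0.027). Leaving out centring and list means, 403 of 417 list medians under the other alternatives kept their call, 9 newly stood apart and 5 no longer did. With list means 8 newly stood apart and 16 no longer did. Genes near the detection level are limited by signal over background.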

Other observations

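The gene families described here were chosen after their values were seen. Gimap genes, GTPases of lymphocyte survival, were lower on the CDR array for 3 of 7 detected members at least 2-fold, with Gimap6 at -2.05, Gimap5 at least 2.19-fold lower and Gimap1 at -1.12 against the non-irradiated array. On the FLASH array 2 of 7 were at least 2-fold lower, and the family stood apart below on both irradiated arrays. Between FLASH and CDR, 4 of 6 detected members were at least 1.5-fold higher, among them Gimap3, at least 1.90-fold higher. The metallothionein genes Mt1 and Mt2, which bind zinc and copper, were at 1.18 and 1.55 on the CDR array and at 0.95 and 1.55 on the FLASH array. Ctla2b was at -1.48 and -1.25, and Gprasp2 was at least 1.97-fold and 1.89-fold lower. Mast cell genes split on both irradiated arrays: the protease gene Tpsb2 was at least 3.34-fold and 6.31-fold higher, Mcpt4 at least 1.29-fold and 1.96-fold higher, and the basophil protease gene Prss34 was lower, at -2.71 and -1.38.

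The fixed endothelial and stromal list did not stand apart between FLASH and CDR, with a median of 0.00, a mean at percentile 97.14 and 1 of 13 detected members, Sparc at 1.2, at least 2-fold higher. Of these members 10 were higher, 4 of them at least 1.5-fold, and 2 lower, Emcn at -0.06 and Pdgfrb at -0.08. Timp3 at 1.24, Gpr182 at 1.01 and Fabp4 at 1.01 were single genes outside that list. Small nucleolar RNA genes differed in the other direction between these arrays, with a median of -0.084 over 107 genes, and 0 of 91 detected were at least 2-fold higher and 1 at least 2-fold lower. Against the non-irradiated array their median was 0.00 on both irradiated arrays. Their mean was 0.10 on CDR, at percentile 99.99, and -0.044 on FLASH, at percentile 20.88. At least 2-fold, 12 were higher and 6 lower on CDR, and 6 higher and 5 lower on FLASH. Single antibody segments were bright on 1 array alone. Of the V segments, 15 were at least 4-fold above both other arrays on the non-irradiated array, 1 on the CDR array and 16 on the FLASH array. Ighv1-9 read 8.98 on the non-irradiated array against 2.18 on CDR and 2.70 on FLASH, and Ighv2-6 read 9.45 on FLASH against 4.77 on the non-irradiated array and 3.75 on CDR. The IgG2c constant region Ighg2c was at -4.50 on CDR and at least 24.7-fold lower on FLASH against the non-irradiated array. Antibody RNA was present without irradiation too, with Igkc at 12.55 and Ighm at 11.83 on the non-irradiated array.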
